A study of Mus musculus with 5 samples.

How the data were processed

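Gene expression was measured by RNA sequencing in 5 libraries of mouse LSK cells, 3 with the control vector and 2 with the miR-99 knockdown vector. The deposited files hold raw read counts per Ensembl gene, 1 file per library. Per the submitters' processing notes, STAR, Picard, HTSeq and DESeq2 and the genome build mm9 were used; versions, the annotation release, the strand setting and the handling of duplicates are not given in the sources used here. The values were whole numbers, no normalization had been applied, and groups and replicate numbers were taken from the labels.

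Each file listed 37620 genes and 5 summary rows, which were left out of library sizes and tests. Reads that the counting assigned to no annotated feature made up 43.3% to 44.8% of all reads listed, and need not lie outside genes. Those aligned to several places made up 19.3% to 21.5%, ambiguous reads 0.158% to 0.173% and unaligned reads 5.33% to 7.46%. Counts assigned to genes came to between 12072745 and 19484020 per library. A floor of 3 counts corresponds to 0.24 CPM in control replicate 1. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Reads aligned to several places are listed in a row of their own rather than under a gene, which lowers the counts of genes with near-identical copies.

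Symbols and 3′ UTR sequences were taken by Ensembl identifier from GENCODE M21, whose build differs from the authors' build, so no coordinates are printed. A symbol was found for 87.4% of the genes. All replicate pairs were compared by a chi-square test of their counts over genes, and none agreed within sampling noise.

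The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with TMM normalization, the filterByExpr filter, robust priors and group as the only term, at a Benjamini-Hochberg adjusted p threshold of 0.05. It covered 14109 genes. The standard error of a log2 fold change is approximate, its size divided by the square root of the F statistic. Gene lists were tested with camera (limma 3.58.1, two-sided, preset inter-gene correlation 0.01), adjusted over the 26 lists. With an estimated correlation 0 lists passed, 4 had an unadjusted p under 0.05, and fry called 6. The seed-site test compared log2 fold changes of protein-coding genes with and without a 7-base match to the miR-99 seed in the longest annotated 3′ UTR, and set the difference against 179 other heptamers of the same base content. Library shares were compared by exact two-sided permutation tests, whose smallest possible p is 0.1 for 3 against 2 libraries.

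The tests, the 26 lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the miR-99 family genes, their neighbours and hosts. It added the 12 largest changes in each direction among genes past the threshold with a mean count of at least 20, an official symbol and no overlap between groups. It then took up to 2 members of each list per direction with the smallest p, and up to 4 seed-site genes, which came to 119 genes. Not all are printed, and some results are not reported here. Gene lists and tests added later are named as such in the closing section.

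On simulated counts for 13809 genes with the same group sizes, the main test recovered 42% of genes changed 2-fold and 78% of genes changed 4-fold, and 4.76% of its calls were unchanged genes. In the same simulation camera gave an adjusted p of 1.04e-09 for a list of 25 genes raised 1.5-fold and called 0 of 26 unchanged lists. With an estimated correlation that raised list had an adjusted p of 0.141, so at these group sizes that setting missed it. Genes were drawn independently of each other. The simulation therefore cannot show how often either setting calls or misses lists whose members vary together, as in real libraries. A seed-site shift of 0.2 on the log2 scale was recovered as 0.174 and passed the threshold.

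Alternatives covered the normalization, the low-count filter, DESeq2 1.42.0, limma-voom, the robust priors, a GC and length offset, a replicate block, the threshold, the list test, the definition of a seed site and leaving out each library.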

Results

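RNA sequencing measured gene expression in mouse LSK cells, the lineage-negative, Sca-1 positive, Kit positive bone marrow fraction that holds haematopoietic stem cells and early progenitors. The cells were infected with a lentiviral vector that carried either a scrambled control sequence or a construct against the microRNA miR-99. GFP-positive cells were sorted 48 hours later. The sample titles mark all 5 libraries as day 2 in vitro and do not say whether the sorted cells still carried the LSK markers. There were 3 control libraries and 2 miR-99 knockdown libraries. The counts assigned to genes were 12072745, 15394482 and 12160184 in control replicates 1 to 3, and 19484020 and 14042880 in knockdown replicates 1 and 2. Genes with at least 1 count numbered between 17067 and 17465 in the controls and between 18020 and 18476 in the knockdown libraries. The labels do not say whether the replicates came from separate mice or cultures, so the p-values measure the spread between these 5 libraries, which may be technical. Within each group the replicates differed by more than sampling noise, and none was counted as a repeat of another. The chi-square per degree of freedom was 76.1 for the knockdown pair and 10.9 to 18.2 for the control pairs. The correlation of log2 CPM was 0.952 for the knockdown pair and 0.97 to 0.975 for the control pairs, so the knockdown libraries differed more. Levels are CPM, counts scaled to a common library size, with the SD over n = 3 control and n = 2 knockdown libraries, and adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14109 tested genes.

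The first question was what the counts show of miR-99 itself. The loci of Mir99a, Mir99b and Mir100, which make up the miR-99 family, had 0 counts in all 5 libraries, as did the neighbouring Mir125a, Mir125b-1, Mir125b-2 and Mirlet7c-1. Counts of this kind do not measure mature microRNAs, so the knockdown could not be checked from them. Mir99ahg, the host transcript of Mir99a, had 7, 0 and 3 counts in the controls and 21 and 6 in the knockdown libraries, too few to test.

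The second question was which genes differed between knockdown and control. The fixed inflammatory and NF-κB list was higher in the knockdown cells and the fixed granulocyte list was lower, and both calls were lost with an estimated correlation (adjusted p = 0.0871 for each). In all, 546 genes changed, of which 443 were higher and 103 lower, and the median change was 3.54-fold among the higher genes and 2.57-fold among the lower ones. At least 4-fold changes were seen in 196 higher and 30 lower genes. All 546 had no overlap between the groups' libraries, which with 3 against 2 libraries nearly follows from passing the threshold. It is therefore no separate support for the calls. Of all tested genes 37.3% had no overlap, against 20% by chance. Leaving out a control library reduced the count to 153 without replicate 1, 77 without replicate 2 and 150 without replicate 3. Leaving out knockdown replicate 1 or 2 raised it to 1059 or 2218, with the lone remaining library assumed to vary like the controls. Of the 60 named genes that changed, 20 passed without each library in turn (Dll4, Fcer2a, Cxcl2, Chil3, Mrc1, Rnf150, Mmp8, Rab3il1, Tcf7, Blnk, Prtn3, Elane, Cd14, Ccr2, Il6, Plk2, Ccl5, Traf1, Klf6 and Cxcl3), and 40 did not pass in at least 1 of these fits.

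The 12 largest increases were in genes of several kinds. Cxcl1, a neutrophil-attracting chemokine, had 0 counts in the controls and 6.41 ± 3.48 CPM in the knockdown libraries, which is at least 28.6-fold higher against a floor of 3 counts per library (adjusted p = 0.00719). Against the same floor it was at least 17.6-fold higher in knockdown replicate 1 and at least 39.6-fold in replicate 2. Csf2, which encodes the cytokine GM-CSF, had 1 control count and 307 knockdown counts, a ratio of 391 with a 95% exact counting interval from 69.6 to 15500. With knockdown replicate 1 or 2 alone the ratio was 612 or 114. Phf11a had 2 and 225 counts (ratio 143, interval 39.2 to 1190), and A1cf had 2 and 119 (ratio 75.7, interval 20.5 to 633). With knockdown replicate 1 or 2 alone the ratio was 243 or 18.6 for Phf11a and 120 or 20 for A1cf. Ptgs2, the inducible cyclooxygenase, rose from 2.74 ± 1.28 to 265 ± 253 CPM (adjusted p = 0.0233), with 444.5 CPM in knockdown replicate 1 and 86.06 in replicate 2, and its fold of 98.2 was 32.3 without replicate 1. Acod1, the itaconate-producing enzyme of activated myeloid cells, rose 74.1-fold, and the chemokine gene Cxcl2 rose 60.5-fold to 115 ± 1.14 CPM. Fcer2a, the low-affinity IgE receptor, rose 76.0-fold from 2.14 ± 0.966 to 165 ± 39.2 CPM (adjusted p = 0.000335). The Notch ligand gene Dll4 rose from 0.170 ± 0.160 to 16.6 ± 1.31 CPM. Gzmc, a granzyme, Sprr2d and Ccdc184 completed the 12 largest increases, with log2 fold changes of 6.58, 7.24 and 6.24. The call of Sprr2d (edgeR adjusted p = 0.0391) was lost with DESeq2 (adjusted p = 0.0696). Gzmc stood at 204.4 and 22.18 CPM in knockdown replicates 1 and 2, Sprr2d at 20.76 and 82.96, Ccdc184 at 4.852 and 11.41, and Acod1 at 548.2 and 144.5. Without knockdown replicate 1 the fold was 18.8 for Gzmc and 31.1 for Acod1, and without replicate 2 it was 60.8 for Sprr2d and 45.1 for Ccdc184. Without a control library the log2 fold change rose to 7.54 for Ccdc184 (replicate 1) and 7.19 for Dll4 (replicate 3). These values rest on at most 0.06413 and 0.1924 CPM in the remaining controls. Sprr2d had 0 CPM in control replicates 1 and 3, so its fold without control replicate 2 cannot be measured. A1cf and Phf11a did not pass without knockdown replicate 1 (adjusted p = 0.185 and 0.222).

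The inflammatory and NF-κB list rose as a group. Of its 29 members 18 rose and none fell over all genes tested, 25 rose when adjusted over the list alone, and all 29 had positive estimates. Its median log2 fold change was 3.0, or 8.0-fold (camera adjusted p = 4.18e-58), and the adjusted p = 0.0871 with an estimated correlation. The median was 3.55 in knockdown replicate 1 and 1.96 in replicate 2, relative to the control mean. Ccl5, a T cell and monocyte chemoattractant, rose 58.3-fold from 20.9 ± 6.54 to 1220 ± 307 CPM. Traf1, a signalling adaptor induced by NF-κB, rose 9.76-fold to 126 ± 35.3 CPM.

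The interferon-response list was higher in the knockdown libraries, mostly in replicate 1: all 34 members lay above every control library in replicate 1 and 30 in replicate 2. Estimates were positive for all 34 members, 3 rose over all genes tested, and 32 rose when adjusted over the list alone. The list median was 3.29 on the log2 scale, or 9.80-fold (camera adjusted p = 2.78e-23), and the adjusted p = 0.373 with an estimated correlation. Relative to the control mean, the median was 4.35 in knockdown replicate 1 and 1.2 in replicate 2, against 0.42 in the highest control library. Ifih1, a sensor of double-stranded RNA, rose from 34.4 ± 4.44 to 147 ± 98.2 CPM (adjusted p = 0.0416), 4.29-fold with both knockdown libraries and 2.3-fold without replicate 1, and Ifitm3, a restriction factor for viral entry, from 461 ± 17.4 to 745 ± 38.4 CPM (adjusted p = 0.025).

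**Figure D1:**
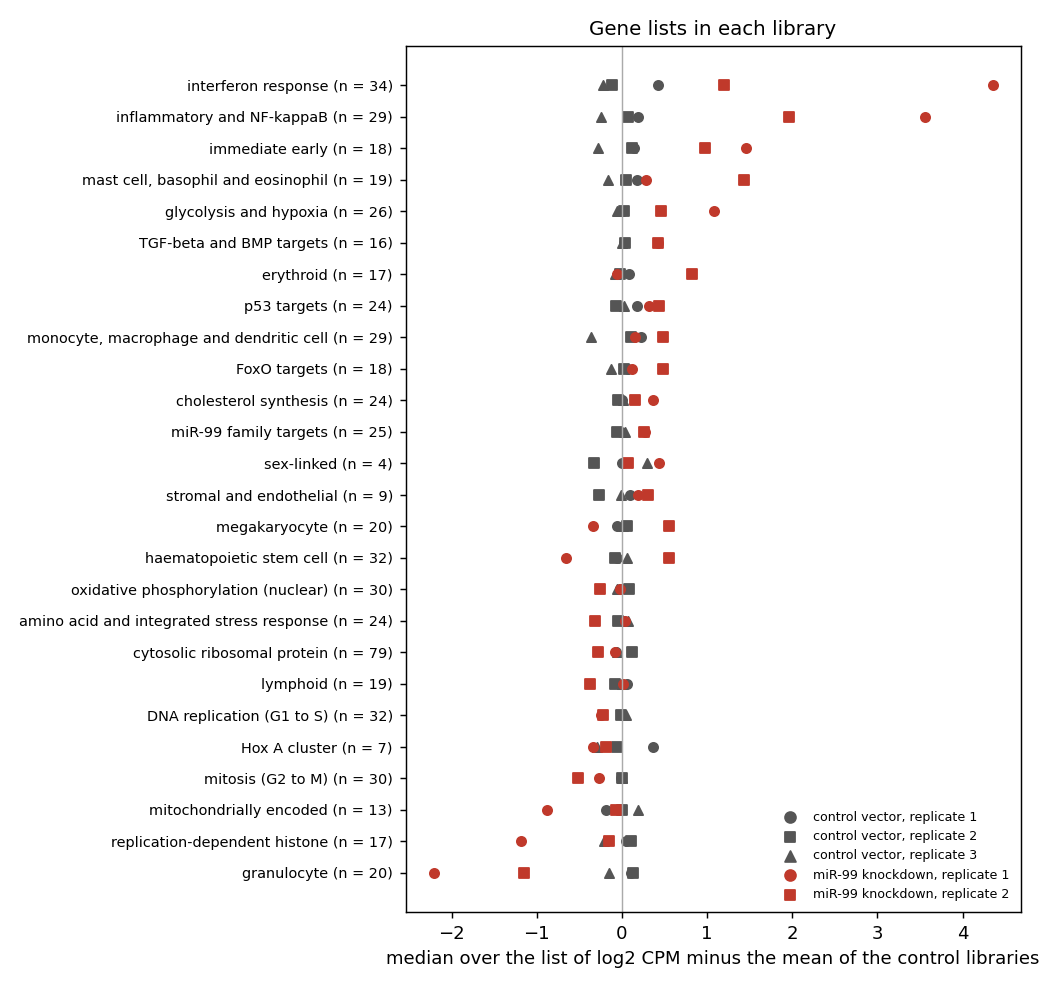
Median, over the tested members of each of the 26 fixed lists, of log2 CPM minus the mean of the control libraries (x axis, log2 units); each symbol is 1 library, grey for the control vector and red for miR-99 knockdown, and n is the number of members. The interferon list stands at 4.35 and 1.2 in the knockdown libraries, and the granulocyte list at -2.21 and -1.15.

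The monocyte, macrophage and dendritic cell list had members that rose and members that fell. Of 29 members 7 rose and 3 fell over all genes, against 9 and 4 adjusted over the list alone, and the list as a whole did not pass (median log2 fold change 0.39, camera adjusted p = 0.164), though it did without knockdown replicate 1 (median 0.47, camera adjusted p = 0.0451). Cd14, a co-receptor for lipopolysaccharide, rose 6.01-fold from 36.4 ± 9.12 to 219 ± 56.6 CPM, and H2-Aa, a class II chain, rose 2.17-fold to 2190 ± 354 CPM. Ccr2, the receptor that guides monocytes to inflamed tissue, fell from 242 ± 35.0 to 44.4 ± 3.96 CPM (adjusted p = 0.00079). Mrc1, the macrophage mannose receptor, fell from 8.52 ± 3.50 to 0.444 ± 0.0693 CPM.

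Granulocyte genes fell. Of 20 members 8 fell and none rose over all genes, and 12 fell and 1 rose when adjusted over the list alone. The median log2 fold change was -1.43 (camera adjusted p = 8.4e-24), and the adjusted p = 0.0871 with an estimated correlation. The median was -2.23 without knockdown replicate 2. Proteinase 3 (Prtn3) fell from 310 ± 29.1 to 50.7 ± 14.9 CPM and neutrophil elastase (Elane) from 213 ± 22.9 to 39.6 ± 9.90 CPM, both serine proteases of primary granules (adjusted p = 0.0011 for both). The collagenase gene Mmp8 fell from 50.3 ± 9.75 to 6.86 ± 0.436 CPM. S100a8 and S100a9, which form calprotectin, had 10.8 ± 0.608 and 3.69 ± 0.577 CPM in the controls and 0.395 ± 0.559 and 0.113 ± 0.160 CPM in the knockdown libraries, where replicate 2 had 0 counts of both. Their log2 fold changes of -4.66 and -4.83 were -3.76 and -3.98 without that library. The secretory granule gene Ngp had a log2 fold change of -5.07, which was -6.54 without knockdown replicate 1 and -4.43 without replicate 2. Chil3, a chitinase-like protein of myeloid cells, had 10.1 ± 3.47 CPM in the controls and 0 counts in the knockdown libraries, at least 53.2-fold lower against the floor of 3 counts per library. Lcn2 went the other way, at 40.1 ± 11.9 and 151 ± 110 CPM, and did not pass over all genes (adjusted p = 0.115).

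**Figure D2:**
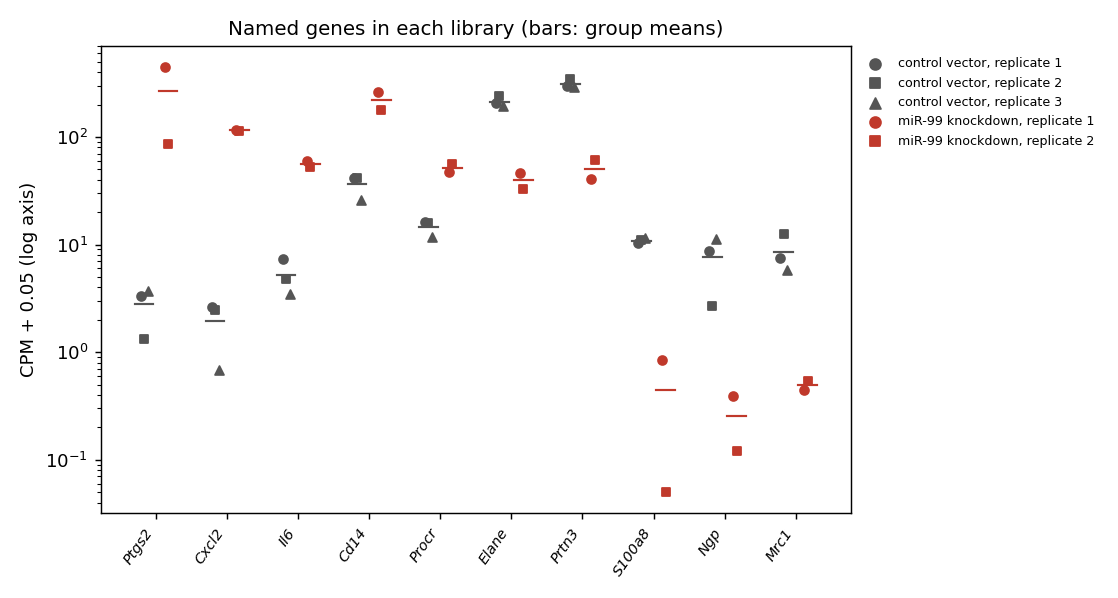
Level of 10 named genes in each library, as CPM plus 0.05 on a log axis; symbols are libraries, grey for the control vector and red for miR-99 knockdown, and bars are group means. Elane stands at 213 CPM on average in the controls and 39.6 in the knockdown libraries, and Cxcl2 at 1.88 and 115.

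Of the 12 largest decreases, Chil3, Ngp, S100a9, S100a8 and Mmp8 are in the granulocyte list and Mrc1 and F13a1 in the monocyte, macrophage and dendritic cell list. F13a1, the A chain of coagulation factor XIII, had a log2 fold change of -3.79, which was -4.55 without knockdown replicate 2, and the thymus-specific protease gene Prss16 had -3.65. Rnf150, Spry1 (an inhibitor of receptor tyrosine kinase signalling), Sgip1 and Rab3il1 had -3.33, -3.25, -3.21 and -2.63, and Sgip1 had -4.26 without knockdown replicate 1. Csf2, Dll4, F13a1, Rnf150, Spry1, Sgip1, Prtn3, Tcf7, Hk2 and Slc7a11 overlap a gene on the opposite strand, as do 193 of the 546 changed genes. Overlap was taken over whole genes, introns included. The share over all tested genes is not given here, so the count is not read as particular to the changed genes. The strand setting of the counting is not given in the sources used here, so reads of such pairs may not be separable.

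Stem cell genes did not move together. Of 32 members 3 rose (4 adjusted over the list alone) and none fell, with 16 positive and 16 negative estimates (median log2 fold change -0.01, camera adjusted p = 0.934). Procr, the endothelial protein C receptor and a stem cell surface marker, rose 3.50-fold from 14.6 ± 2.45 to 51.2 ± 6.27 CPM, and Slamf1 (CD150) rose 7.40-fold to 11.4 ± 4.02 CPM. Cd34 stood at 952 ± 15.2 and 666 ± 251 CPM (adjusted p = 0.236). The list went opposite ways in the knockdown libraries: its median was -0.69 without knockdown replicate 2 (camera adjusted p = 0.0033) and 0.55 without replicate 1 (camera adjusted p = 0.00338).

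In the lymphoid list 4 of 19 members rose and 2 fell (5 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.491). Tcf7, a T lineage transcription factor, rose 5.08-fold to 21 ± 0.441 CPM and the B cell adaptor gene Blnk rose 5.14-fold to 48.6 ± 11.9 CPM. Dntt, the terminal transferase of early lymphoid cells, fell from 15.1 ± 2.30 to 3.82 ± 2.42 CPM, with a log2 fold change of -1.97, or -2.82 without knockdown replicate 1. The mast cell, basophil and eosinophil list rose (median 0.83, camera adjusted p = 0.000156, adjusted p = 0.331 with an estimated correlation). Of its 19 members 3 rose (6 over the list alone), among them the cytokine gene Il6, which many activated cells express, 10.9-fold to 55.8 ± 4.93 CPM. Its median was 0.26 without knockdown replicate 2, where it did not pass (camera adjusted p = 0.13). The erythroid list passed too (median 1.0, camera adjusted p = 0.0112, adjusted p = 0.513 with an estimated correlation), but relative to the control mean its median was -0.05 in knockdown replicate 1 and 0.82 in replicate 2. It had 2 of 17 members called higher (4 rose and 1 fell over the list alone). Its camera adjusted p was 0.104 without knockdown replicate 2. The called members were a beta globin gene, Hbb-bs, which rose 3.91-fold, and carbonic anhydrase 2 (Car2), which is not confined to red cells and rose 2.86-fold to 3070 ± 948 CPM. Hbb-bs has a near-identical copy, so its count is uncertain. In the megakaryocyte list 1 of 20 members rose, Itgb3, 1.82-fold (list camera adjusted p = 0.51). Its median was -0.34 in knockdown replicate 1 and 0.56 in replicate 2 relative to the control mean, and the list passed without replicate 1 (camera adjusted p = 0.00338). In the stromal and endothelial list 1 of 9 rose, Lum, 6.25-fold (list camera adjusted p = 0.265).

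Stress and signalling lists rose in part. The immediate early list had 4 of 18 members higher (12 rose and 1 fell over the list alone) and a median of 1.54 (camera adjusted p = 3.2e-10, adjusted p = 0.165 with an estimated correlation), including Klf6, 4.21-fold, and Ier3, 3.43-fold. In the p53 target list 3 of 24 rose (6 rose and 2 fell over the list alone), with a median of 0.38 (camera adjusted p = 0.000277, adjusted p = 0.165 with an estimated correlation). They include the kinase gene Plk2, from 10.9 ± 2.94 to 195 ± 28.0 CPM, and the death receptor gene Fas, from 9.24 ± 1.34 to 64.0 ± 38.2 CPM, 6.92-fold, or 4.04-fold without knockdown replicate 1. All 26 glycolysis and hypoxia genes had positive estimates, 4 rose over all genes and 21 over the list alone, with a median of 0.99 (camera adjusted p = 4.47e-13, adjusted p = 0.373 with an estimated correlation). Hexokinase 2 (Hk2) rose 2.51-fold and the phosphofructokinase gene Pfkl 2.14-fold. The median was 0.46 without knockdown replicate 1.

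Proliferation and ribosomal lists fell by small amounts. The mitosis list had a median of -0.37 (camera adjusted p = 5.31e-06, adjusted p = 0.331 with an estimated correlation), with 1 of 30 members called over all genes and 8 over the list alone. The called member, the cytokinesis motor gene Kif23, fell from 180 ± 29.5 to 98.1 ± 1.98 CPM (adjusted p = 0.0314). The DNA replication list had a median of -0.19 (camera adjusted p = 0.00611, adjusted p = 0.331 with an estimated correlation), with 0 of 32 members called by edgeR (7 at an unadjusted p under 0.05, and 1 by DESeq2). Cytosolic ribosomal protein genes had a median of -0.17, with 76 of 79 estimates below 0 (camera adjusted p = 0.000518, adjusted p = 0.696 with an estimated correlation). Their median was -0.09 without knockdown replicate 2, where they did not pass (camera adjusted p = 0.13), -0.08 without control replicate 2 and -0.26 without knockdown replicate 1. Mitochondrially encoded genes had a median of -0.44 (camera adjusted p = 0.0272, adjusted p = 0.694 with an estimated correlation). Their median was -0.09 without knockdown replicate 1 and -0.90 without knockdown replicate 2, so it rests mostly on replicate 1. They did not pass without control replicate 3 (-0.21, camera adjusted p = 0.104). Replication-dependent histone genes had a median of -0.71 (camera adjusted p = 0.0271, adjusted p = 0.633 with an estimated correlation) and -1.49 without knockdown replicate 2. The list did not pass without knockdown replicate 1 (-0.46, camera adjusted p = 0.383), control replicate 1 (camera adjusted p = 0.0591) or control replicate 2 (camera adjusted p = 0.134). In these last 3 lists edgeR and DESeq2 each called 0 members, and 2 ribosomal protein, 0 mitochondrially encoded and 6 histone genes had an unadjusted p under 0.05.

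The remaining lists did not pass camera with all 5 libraries. They were the Hox A cluster (median -0.10), the amino acid and integrated stress response (-0.20, with the cystine transporter gene Slc7a11 higher 4.07-fold, or 2.62-fold without knockdown replicate 1), cholesterol synthesis (0.26), nuclear oxidative phosphorylation (-0.13), FoxO targets (0.28), TGF-β and BMP targets (0.45) and sex-linked genes (0.25). Oxidative phosphorylation passed without knockdown replicate 1 (-0.25, camera adjusted p = 0.00136) and without control replicate 3 (camera adjusted p = 0.0374), and cholesterol synthesis without knockdown replicate 2 (0.36, camera adjusted p = 0.0173). The TGF-β and BMP list passed fry (adjusted p = 0.00947). Among TGF-β and BMP targets the cell cycle inhibitor gene Cdkn2b rose from 0.182 ± 0.176 to 5.15 ± 1.5 CPM (25.8-fold, or 58.7-fold without control replicate 2), Skil rose 2.49-fold, and Id3 fell from 9.31 ± 2.98 to 2.47 ± 0.501 CPM. The higher Cdkn2b fold rests on 0.08013 and 0.07961 CPM in control replicates 1 and 3.

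The last question was whether transcripts with miR-99 sites rose in the knockdown cells. No shift of genes with a seed match in the 3′ UTR was detected: the median log2 fold change was -0.01 for 278 genes with a match and -0.02 for 11443 without one. The difference of 0.0073 had a 95% bootstrap interval over genes from -0.0541 to 0.118, and camera on edgeR's fit did not pass the threshold of 0.05. Of the genes with a match 9 rose and 1 fell, and the share that rose was 3.24%, against 3.55% without a match (two-sided Fisher's exact test p = 1). Without knockdown replicate 2 these shares were 14.9% and 10.5% (two-sided Fisher's exact test p = 0.024). For the 165 genes with the match to seed positions 2 to 8 the difference was 0.106, which did not pass either. This was at percentile 92.2 among 179 control heptamers of the same bases, 14 of which gave a difference as high. The called genes with a match include Cxcl3, a chemokine, which rose 46.1-fold to 51.5 ± 6.35 CPM, Ankrd33b, 4.82-fold, Pkib, a protein kinase A inhibitor, 2.40-fold, and Rnf150, which fell. The list of published or predicted miR-99 targets had 0 of 25 members called by edgeR over all genes or over the list alone (7 at an unadjusted p under 0.05, and 2 by DESeq2), 17 positive and 8 negative estimates and a median of 0.28 (camera adjusted p = 0.164, fry adjusted p = 0.0715). Trib1 stood at 1.28 ± 0.793 and 5.41 ± 0.712 CPM (adjusted p = 0.0732).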

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

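The share of unaligned reads, which enters none of the comparisons, was higher in the knockdown libraries than in the controls. It was 7.36% ± 0.141 (SD, n = 2) in the knockdown libraries and 5.73% ± 0.367 (SD, n = 3) in the controls, and both knockdown libraries lay above every control library (exact two-sided permutation p = 0.1, the smallest that 3 against 2 libraries can give). The unaligned reads themselves were not analysed here. Reads aligned to several places (mean 19.3% in the knockdown libraries, 20.9% in the controls) reached the same permutation p. So did the share of counts in the 10 highest genes (7.06% and 5.75%) and the number of genes detected. The shares of reads assigned to no feature and of mitochondrially encoded counts did not (permutation p = 0.3 and 0.4).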

How the results depend on the processing

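All alternatives here were planned. Every gene called in the main test and tested in an alternative kept its direction in all 16 refits, while the number of calls varied widely. Against 546 genes (443 higher, 103 lower), the total was 866 without a low-count filter (214 lower), 1317 with DESeq2 (935 higher, 382 lower) and 1031 at an adjusted p of 0.1 (746 higher, 285 lower). limma-voom with quality weights called 50 lower genes. Leaving out 1 library gave 77 to 2218 genes, 64 to 1409 higher and 13 to 809 lower. Fits without a control library gave 77 to 153, and fits without a knockdown library 1059 to 2218 with a single knockdown library left. The replicate block gave 250 genes (210 higher, 40 lower), of which 211 were among the 546, and with the GC and length offset in the same fit 504. Samples with the same number did not deviate together (correlation across genes -0.000552 for replicate 1 and 0.0384 for replicate 2, 2 pairs). With 2 knockdown libraries their deviations are mirror images, so both values use the same knockdown difference and cannot exclude a shared animal or day. The labels do not say that the numbers pair the samples, so the block was kept as an alternative only. For the lists, 13 were called by camera, 0 with an estimated correlation, 6 by fry, 12 with the replicate block and 12 to 15 when 1 library was left out. The stem cell list, not called with all libraries, passed in opposite directions, at a median of -0.688 without knockdown replicate 2 and 0.55 without replicate 1. The seed-site difference was 0.007, ranged from -0.014 to 0.077 when 1 library was left out, was 0.045 with the replicate block and -0.039 against a matched background, and did not pass camera under any of its alternatives. The share of site genes that rose passed Fisher's exact test only without knockdown replicate 2 (42 of 282 genes, 14.9% against 10.5%, p = 0.024). Of the 119 named genes none changed direction where called. The cause of these differences was not tested, except that a fit without a library rests on fewer samples. With 3 and 2 libraries, changes near 2-fold are often missed, as the simulation in the methods shows.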

Other observations

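The 4 lists and the tests of explanations in this part were chosen after the results were seen, and many members of the lists were known to be called when they were written, so their p-values are not independent evidence. Genes of dendritic cell maturation were higher in the knockdown cells: 18 of 24 tested members rose and none fell (median log2 fold change 2.32, camera p = 1.4e-47, p = 0.00188 with an estimated correlation), and the median was 2.39 in knockdown replicate 1 and 2.47 in replicate 2. The list shares 2 genes with the NF-κB list. Ccl22, a chemokine of activated dendritic cells, rose from 130 ± 46.9 to 2630 ± 1890 CPM, and Ccr7, their lymph node homing receptor, from 50.5 ± 9.89 to 246 ± 37.4 CPM. The actin-bundling gene Fscn1 rose from 2.19 ± 0.697 to 35.9 ± 4.68 CPM.

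Genes of MHC class I presentation rose by less, with 11 of 20 members called higher and a median of 0.76 (camera p = 1.64e-12, p = 0.0523 with an estimated correlation), including H2-K1 from 798 ± 41.4 to 1350 ± 131 CPM. In the class II list, which shares 5 genes with the monocyte, macrophage and dendritic cell list, those 5 of 8 members rose, with a median of 1.10 (camera p = 2.34e-10, p = 0.0449 with an estimated correlation), and the invariant chain gene Cd74 went from 4510 ± 483 to 9590 ± 1720 CPM. Ribosome biogenesis genes had 4 of 30 members lower and 28 estimates below 0, with a median of -0.47 (camera p = 1.7e-08, p = 0.0717 with an estimated correlation). Grwd1 fell from 96.3 ± 6.71 to 50.4 ± 11.1 CPM.

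The first pattern is the rise of NF-κB, cytokine and interferon genes. The NF-κB and interferon list medians exceeded that of the monocyte, macrophage and dendritic cell list by 2.62 and 2.91 on the log2 scale. The 95% bootstrap intervals over genes were 1.27 to 3.43 and 1.81 to 3.86. These differences alone do not decide on a larger share of those cells, since genes also expressed in other cells would rise by less. Members of their list moved apart: 7 rose, from 2.12-fold for Cd74 to 6.01-fold for Cd14, and Ccr2, Mrc1 and F13a1 fell. This argues against an equal rise in the share of all such cells already present in the controls as the only change. Members would also move apart if expression within those cells changed, so such a rise is not excluded. A larger share of the cells that express the 7 stays open. With the GC and length offset the median was 3.0 for the NF-κB list (interval 1.79 to 3.43) and 3.27 for the interferon list (interval 2.37 to 4.05), which argues against that bias for both, although 15 rather than 18 and 2 rather than 3 members were then called. The NF-κB list's median in the weaker knockdown library, 1.96 (interval 1.55 to 3.01), lay above the highest control library, 0.19. This argues against a rise in 1 knockdown library alone for that list. The interval resamples genes of 1 library and leaves out the spread between libraries. For the interferon list, 1.2 in the weaker library (interval 0.88 to 1.46) lay above the highest control library, 0.42, and 30 of the 34 members lay above every control library. Its lower bound did not clear the highest control by the range of the controls, a limit of 1.05 that had been made stricter after the value passed a looser one, so how far the rise rests on 1 library stays open. A response to the vector or the infection, more mature dendritic cells, and the knockdown itself may each account for the pattern and were not separated by any test. The lineage-negative gate of LSK cells would remove cells that carried lineage markers when it was applied. Cells that gained such markers in culture after that step would remain.

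The second pattern is the fall of granulocyte genes. Dilution of all progenitors by other cells is argued against as the source of the whole fall. This holds only if the stem cell list stands for all progenitors and its own genes did not change in expression. The intervals, over genes, leave out the spread between libraries. The stem cell list's median was -0.66 (interval -0.97 to -0.43) in knockdown replicate 1 and 0.55 (interval 0.15 to 0.75) in replicate 2. Both lay above that of the granulocyte list, -2.21 and -1.15. With both libraries the stem cell median was -0.01 (interval -0.34 to 0.21), though they went opposite ways. A partial dilution in knockdown replicate 1, where the stem cell interval was negative throughout, stays open. GC content and length are argued against by a median of -1.41 (interval -2.48 to -1.04) with the offset. A smaller share of granulocyte-primed progenitors and lower expression within them may both apply and were not tested.

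Of the 10 splits of the 5 libraries into 3 and 2, only 1, the real one, gave as many changed genes: 546, against a highest of 0 among the others. With 10 splits the share cannot fall under 0.05.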
